A study of Mus musculus with 8 samples.

How the data were processed

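RNA was measured in 8 bulk tongue libraries, 4 from WT and 4 from A17/+ female mice aged 12 months, with mcSCRB-seq. This method tags the 3' end of each polyadenylated RNA with a sample barcode and a unique molecular identifier (UMI), so that copies made by amplification are counted once. Per the labels, total RNA came from cryosections of the middle of the tongue, and a well barcode was added to every sample at reverse transcription. The labels name cutadapt 2.10, STAR 2.7.5a, UMI-tools 1.1.1 and HTSeq without a version, and the genome build mm10. They give no settings, strand or annotation release. The deposited table holds raw counts per Ensembl gene identifier for the 8 libraries, as whole numbers that differ in total between libraries. The deposited file of each library holds log2 values for 10709 genes. These log2 values fitted a base-2 logarithm of CPM (counts scaled by the library total, in the usual unit) with a scaled library size and a mean prior count of 2.00, and the largest error of that fit over the libraries was 4.38e-08.

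The deposited counts were analysed, and the deposited log2 values were used in alternatives only. Symbols, positions and transcript lengths were taken from GENCODE for the mouse build that matches mm10, by Ensembl identifier. Of 19857 genes in the table, 19677 had a symbol there, and the other 180 kept their identifiers. Genes with too few counts were left out with filterByExpr (minimum count 10, minimum total count 15), which kept 5066 genes. Libraries were scaled by TMM and fitted with the robust quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with genotype as the only term. Replicate numbers were not used as pairs, because the labels do not say that equal numbers belong together. P-values were adjusted by Benjamini and Hochberg, and 0.05 was the threshold. Log2 fold changes are A17/+ minus WT. Levels are CPM with TMM scaling, as mean ± SD over 4 libraries. Single measures were compared with a two-sided exact permutation test over the 70 assignments of the libraries, whose smallest possible p is 0.0286.

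Before the data were examined, the comparison, the filter, the tests, the rule for named genes and 35 gene lists were fixed, together with the first set of alternatives below. The named genes are Pabpn1 and, per direction, the 10 genes with the largest fold change among those past the threshold whose 4 A17/+ values all lay on 1 side of the 4 WT values, leaving out predicted genes. Up to 4 members of each list with the smallest p among those past the threshold were added, or up to 2 as values only where none passed. A few genes that the rule named are not reported here. Other genes named in the text were chosen after their values were seen and are said to be so. Lists with at least 5 tested members, 30 in all, were compared with the remaining genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, and fry, which tests a list on its own, were alternatives.

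The fit was tested on simulated data with the libraries' own depth. Of 100 genes changed 2-fold it recovered 54%, and of 100 genes changed 4-fold 98%, none with the wrong sign, and 5% of the calls were false. Simulated groups without a difference gave 0 genes and 0 lists. The simulated genes varied independently of each other, whereas the estimated correlation within a real list reached 0.674. These rates, above all the 0 lists, therefore need not hold for the real libraries. Library totals ran from 205696 to 485326 UMIs. A gene at 10 CPM is therefore a few molecules in a library, and single-library values at that level carry a large counting error.

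Alternatives were other scalings (relative log expression, upper quartile, library totals only), DESeq2 1.42.0, limma-voom with and without sample weights, other filters, the replicate number as a block, removal of mitochondrial transcripts, a tongue epithelium covariate, an adjusted p under 0.1, and leaving out each library. Further alternatives were added after the data were seen: a transcript length trend removed from each library by loess, counts thinned to the smallest library, edgeR on the genes of the deposited log2 values, limma-trend on those values, and both libraries numbered 1 left out. The planned edgeR test of Pabpn1 was not used because the gene lay below the filter, and an exact permutation test took its place. A covariate of salivary gland genes was not run because none of them passed the filter.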

Results

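The tongues of 12-month-old female mice that carry the A17 allele of Pabpn1 on 1 chromosome (A17/+) were compared with those of wild type (WT) mice, with 4 mice per genotype. A17/+ mice are a model of oculopharyngeal muscular dystrophy, a late-onset disease of the eyelid, throat and tongue muscles, and PABPN1 is a nuclear protein that binds the poly(A) tail. The libraries of a group were separate animals according to the labels. The p-values of single genes and of the permutation tests rest on the spread between these animals. The p-values of camera with the preset correlation compare the members of a list with the remaining genes. They do not measure how far a list as a whole varies between animals. The WT libraries 1 to 4 held 465014, 297294, 314493 and 205696 UMIs, and the A17/+ libraries 1 to 4 held 485326, 419518, 395061 and 421409. Mean totals of 320624 in WT and 430329 in A17/+ gave an exact permutation p of 0.114. More genes were detected in A17/+ (14314 ± 94.5, SD, n = 4) than in WT (12784 ± 1163, SD, n = 4; exact permutation p = 0.0286). Within WT they ran from 11339 in WT 4, the smallest library, to 14164 in WT 1, the largest. Depth and genotype are therefore not separated in this measure. A single identifier without a symbol, ENSMUSG00000119584, took 11.3% to 14.9% of the counts of each library. Ttn, the giant spring protein of the sarcomere, which like that identifier was chosen after its values were seen, took 6.04% ± 0.512 in WT and 6.08% ± 1.02 in A17/+ (SD, n = 4).

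Libraries differed in ways beyond single genes. The first principal component held 50.2% of the variance and placed WT 1 to 4 at −7.21, −19.8, −28.2 and −35.8 and A17/+ 1 to 4 at 4.27, 29.1, 27.0 and 30.7, so that WT 1 and A17/+ 1 lay nearest to the other genotype. Across genes, WT 1 correlated more with A17/+ 1 (Pearson r of log2 CPM 0.927) than with any WT library (highest 0.904), and A17/+ 1 more with WT 1 than with any A17/+ library (highest 0.897). On the second component they lay at 19.6 and 18.4, and the other libraries between −25.8 and 5.05. Transcripts shorter than 1000 nt took 4.76% ± 0.30 of the counts in WT and 7.58% ± 2.07 in A17/+ (SD, n = 4; exact permutation p = 0.0571), and A17/+ 1 had 5.04%. Transcripts of the mitochondrial genome took 5.17% ± 0.949 in WT and 8.71% ± 1.60 in A17/+ (SD, n = 4; exact permutation p = 0.0286). Lipf, Dmbt1, Bpifb1, Amy1 and Muc5b, which encode secreted products of salivary glands and were chosen after their values were seen, had 418, 239, 188, 41 and 36 counts in WT 1. The whole list of lingual salivary gland genes summed to 941 counts in WT 1 and to 1 to 7 in the other WT libraries.

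The first question was whether the altered gene itself had another RNA level. Pabpn1 (ENSMUSG00000022194, mm10 chromosome 14, 54892500 to 54898169, plus strand) had 15, 4, 6 and 6 counts in WT 1 to 4 and 9, 9, 5 and 11 in A17/+ 1 to 4. Its level was 24.8 ± 9.92 CPM in WT and 22.7 ± 7.37 CPM in A17/+ (SD, n = 4), a log2 ratio of −0.12 with an exact permutation p of 0.714. The edgeR fit on all detected genes gave −0.19 with a 95% interval from −1.28 to 0.90, a fold of 0.412 to 1.86, so no difference was detectable at this depth and differences inside that interval are not excluded. The log2 ratio of mean CPM was 0.02 without WT 1. Without A17/+ 3 the gene passed the filter, and its edgeR log2 fold change was 0.03. A read-through gene model, Gm20521 (54883441 to 54898137), overlaps Pabpn1 and is absent from the count table. Counts at the 3' end do not read the changed stretch of the protein and do not check the genotype.

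The second question was which genes differed between A17/+ and WT tongue. Genes of mitochondrial respiration, ribosomes and fast muscle were the main groups higher in A17/+, and the genes lower in A17/+ changed by smaller factors. With an estimated correlation these 3 lists had adjusted p of 0.195, 0.265 and 0.195, the genes of respiration and ribosomes have short transcripts, and A17/+ 1 lay near WT for both. Hbb-bs, a beta-globin chain of haemoglobin, rose most, 37.8-fold, from 7.13 ± 2.67 to 262 ± 290 CPM (SD, n = 4), and its near-identical copies make the assignment of globin reads uncertain. A17/+ 2 held 244 of its 375 counts in A17/+, and its log2 fold change of 5.24 was 4.11 without that library. Its adjusted p was 0.0637 without WT 1, 0.0535 without WT 2, 0.0759 without WT 3, 0.0557 without WT 4 and 0.0586 without A17/+ 4. Cox7a1, the muscle form of a cytochrome oxidase subunit, rose 32.7-fold from 8.88 ± 9.47 to 370 ± 230 CPM. Atp5g1, the ring subunit of ATP synthase, rose 29.9-fold from 14 ± 11.9 to 466 ± 273 CPM. Pvalb, the calcium buffer parvalbumin of fast fibres, rose 20.4-fold from 4.43 ± 3.73 to 107 ± 55.5 CPM, and Sln, the calcium pump regulator sarcolipin, rose 17.8-fold from 30.0 ± 15.6 to 572 ± 374 CPM. The other genes among the 10 largest rises were Rps21 (log2 fold change 4.67), Atp5e (4.33), Atp5mpl (4.31), Ndufc1 (4.30) and Uqcr11 (4.16), which encode a ribosomal protein and parts of ATP synthase and of respiratory complexes.

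Among the genes that fell, Epgn, a ligand of the epidermal growth factor receptor, had the largest change, from 42.0 ± 16.7 to 10.7 ± 2.65 CPM (log2 fold change −1.94). Cry2, a repressor of the circadian clock, fell from 67.6 ± 45.4 to 17.7 ± 9.46 CPM (log2 fold change −1.81). Thbs2, a thrombospondin of the extracellular matrix, fell from 46.6 ± 12.9 to 14.1 ± 4.12 CPM (−1.72), and Fbp2, the muscle fructose bisphosphatase, fell from 37.2 ± 9.57 to 11.3 ± 6.15 CPM (−1.65). The others were Mctp2 (−1.70), the unnamed ENSMUSG00000118671 (−1.59), Atad5 (−1.55), Fam196b (−1.53), Rbm15b (−1.49) and Cttnbp2 (−1.48). Adjusted p ranged from 0.00278 for Pvalb to 0.0268 for Fbp2 over these 20 genes, and each had all 4 A17/+ values on 1 side of the 4 WT values. Of the 20, 12 missed the threshold without WT 3, 6 without A17/+ 3, 5 without WT 4 and 4 without WT 2. Without A17/+ 4 it was 4, without WT 1 it was 3, without A17/+ 2 it was 1 and without A17/+ 1 it was 0.

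**Figure D1:**
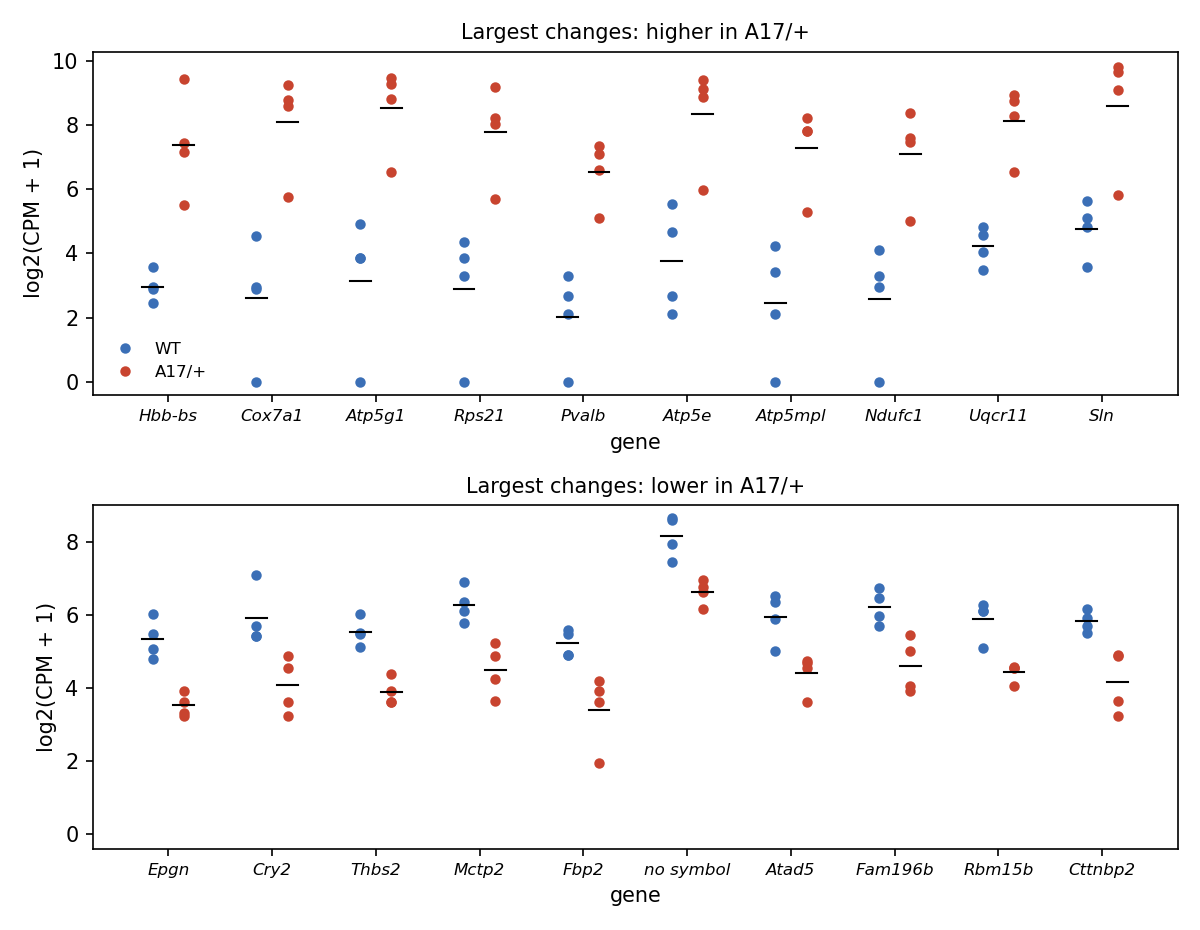
Level of the genes with the largest changes in each library, as log2 of CPM plus 1, with a point per library and a black line at the mean of the 4 libraries of a genotype. For every gene the 4 A17/+ points lie on 1 side of the 4 WT points, and the gene without a symbol is ENSMUSG00000118671.

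Of 5066 genes tested with edgeR, 321 were higher and 132 were lower in A17/+, and 1273 had an unadjusted p under 0.05. Of the genes that changed, 267 were higher and 48 lower by more than 2-fold. The 4 A17/+ values lay apart from the 4 WT values for 742 genes, 14.6% of those tested against 2.86% expected by chance, and for 372 of the 453 genes that changed. With library totals in place of TMM the median of all genes moved by −0.12 and the split became 279 higher and 289 lower. With a transcript length trend removed from each library it was 266 higher and 174 lower. The count of 453 became 890 without WT 1, 210 without WT 3, 771 without A17/+ 1, 247 without A17/+ 3 and 232 without A17/+ 4. The 132 genes lower became 383 without WT 1, 69 without WT 2, 38 without WT 3, 226 without A17/+ 2, 52 without A17/+ 3 and 51 without A17/+ 4. Of the 88 named genes past the threshold, 39 missed it without WT 3, 23 without A17/+ 3, 21 without A17/+ 4, 21 without WT 4, 20 without WT 2, 11 without A17/+ 2, 4 without WT 1 and 0 without A17/+ 1.

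Nuclear genes of oxidative phosphorylation, which build the respiratory chain and ATP synthase, formed the list with the largest median rise. Of 63 measured members 52 rose and 0 fell, 56 rose when adjusted over the list alone, and the median log2 fold change was 2.48 (camera adjusted p = 5.33e-45). The list's adjusted p was 0.195 with an estimated correlation. Examples were Uqcrb (log2 fold change 2.21), Cox6c (2.60), Ndufs6 (3.09) and Uqcrfs1 (1.75), subunits of complexes III, IV, I and III. The members together took 0.971% ± 0.0896 of the TMM-scaled counts in WT and 2.29% ± 0.703 in A17/+ (SD, n = 4; exact permutation p = 0.0286). A17/+ 1, at 1.32%, was nearest to the WT libraries, whose highest was 1.09%. The median transcript length of the members was 838 nt.

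Transcripts of the mitochondrial genome were also higher: 7 of 9 measured members were higher and 0 lower, 7 when adjusted over the list alone, with a median log2 fold change of 0.87 (camera adjusted p = 6.98e-10). They took 9.04%, 8.57%, 9.21% and 13.2% of the TMM-scaled counts in A17/+ 1 to 4, and at most 6.67% in WT. A17/+ 1 thus did not lie near WT here, and A17/+ 2, highest for oxidative phosphorylation, was lowest of its genotype. With an estimated correlation the adjusted p was 0.195. The complex I and III subunits mt-Nd1 (1.58), mt-Cytb (2.68), mt-Nd2 (2.92) and mt-Nd4 (2.03) rose. The ribosomal RNAs mt-Rnr2 and mt-Rnr1, chosen after their values were seen, had 0.87 (adjusted p = 0.0102) and 0.43 (adjusted p = 0.232). Fatty acid oxidation genes had 6 of 19 members higher and 0 lower, 10 when adjusted over the list alone, a median of 0.79 and a camera adjusted p of 3.06e-07. Their adjusted p was 0.163 with an estimated correlation. Fabp3, a fatty acid carrier, rose by 3.12 on the log2 scale, Hadhb and Hadha, the subunits of the trifunctional enzyme, by 1.74 and 0.77, and Cd36, a fatty acid transporter, by 0.87.

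**Figure D2:**
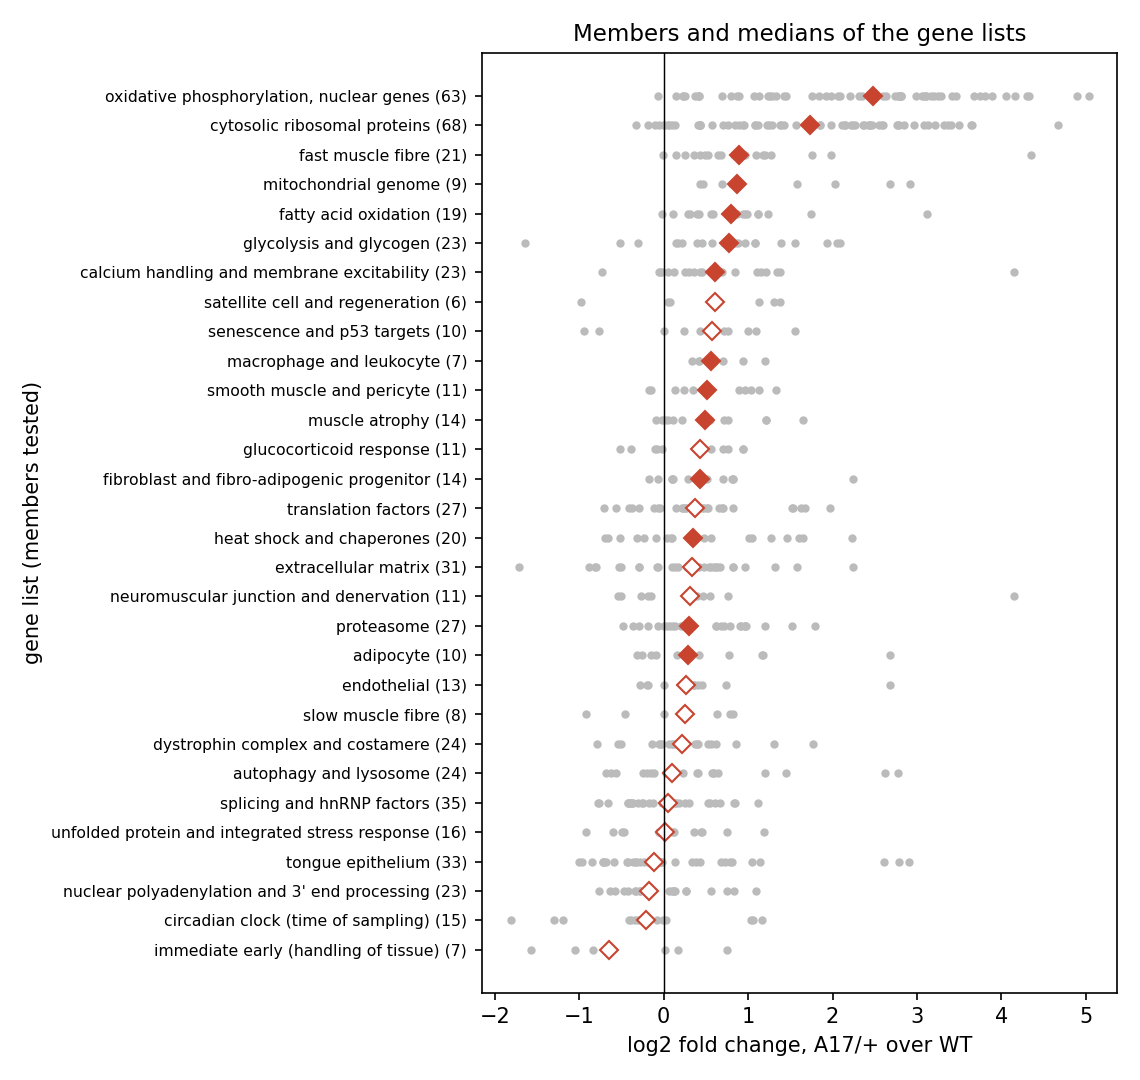
Log2 fold change, A17/+ minus WT, of the members of each gene list (grey dots) with the list median (diamonds, filled where the camera adjusted p is under 0.05). The medians of oxidative phosphorylation (2.48) and cytosolic ribosomal proteins (1.73) lie farthest to the right.

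Cytosolic ribosomal protein genes were the other large group. Of 68 measured members 25 rose and 0 fell, 50 rose when adjusted over the list alone, and the median was 1.73 (camera adjusted p = 1.06e-20). The adjusted p was 0.265 with an estimated correlation. Rpl36a (log2 fold change 2.15), Rpl34 (2.22) and Rpl18 (2.26) were among the members with the smallest p. The genome holds many near-identical processed copies of these genes, so the assignment of their reads to a single gene is uncertain. Their summed share was 0.575% ± 0.142 in WT and 1.42% ± 0.671 in A17/+ (SD, n = 4; exact permutation p = 0.0857), and A17/+ 1 had 0.627%, inside the WT range. Translation factors did not pass as a list (camera adjusted p = 0.0680), although 5 of 27 members rose over all genes and, when adjusted over the list alone, 5 rose and 2 fell. The initiation factors Eif1 (1.62), Eif3h (1.67), Eif3m (1.52) and Eif3f (1.53) rose. That list had an adjusted p of 0.0369 without A17/+ 3, 0.0370 without A17/+ 4 and 0.0296 with no filter.

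Fast muscle fibre genes rose as a group, with 12 of 21 members higher and 0 lower, 16 when adjusted over the list alone, and a median of 0.89 (camera adjusted p = 1.59e-10). The adjusted p was 0.195 with an estimated correlation. Besides Pvalb, Myoz1, a Z-disc protein, rose by 1.99 on the log2 scale, Myl1, a myosin light chain, by 1.76, and Ckm, muscle creatine kinase, by 1.09. The list took 3.87% ± 0.590 of counts in WT and 5.14% ± 0.418 in A17/+ (SD, n = 4; exact permutation p = 0.0286). Myh4, the heavy chain of fast glycolytic fibres and not among the genes named by the rule, was chosen after its value was seen and had −0.01. Of 8 slow fibre genes, 0 were higher and 1, the tropomyosin Tpm3 (−0.92), was lower, against 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.576). For the slow fibre list the limma fry adjusted p was 0.0604.

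Glycolysis and glycogen genes rose with the fast fibre genes. Of 23 members 11 were higher and 1, Fbp2, was lower, 16 and 1 when adjusted over the list alone, with a median of 0.77 (camera adjusted p = 1.13e-07). The adjusted p was 0.209 with an estimated correlation. Ldhb (2.05) and Ldha (1.55), the lactate dehydrogenase chains, Tpi1 (2.09), triosephosphate isomerase, and Pfkm (1.09), muscle phosphofructokinase, were examples. Calcium handling and membrane excitability genes had 8 of 23 members higher and 0 lower, 11 when adjusted over the list alone, a median of 0.61 and a camera adjusted p of 6.69e-05. Their adjusted p was 0.195 with an estimated correlation. Sln (4.15), the sodium pump chain Atp1b1 (1.35) and the calmodulin gene Calm2 (1.16) were among those that rose.

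Lists of muscle wasting and protein turnover had smaller medians. Muscle atrophy genes had 3 of 14 members higher and 0 lower, 4 when adjusted over the list alone, a median of 0.48 and a camera adjusted p of 0.0153. Their adjusted p was 0.202 with an estimated correlation. Trim63 (1.21), the ubiquitin ligase MuRF1, and Igfbp5 (0.72), a growth factor binding protein, were among the members that rose. Proteasome genes had 3 of 27 members higher and 0 lower, 5 when adjusted over the list alone, a median of 0.30 and a camera adjusted p of 0.0153. Their adjusted p was 0.250 with an estimated correlation. The call was lost without A17/+ 1 (0.0589, median 0.53), with counts thinned to the smallest library (0.122, median 0.34) and with the length trend removed (0.285, median 0.13). Psmb1 (1.79), Psmb4 (1.52) and Psmc6 (0.97) rose.

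Heat shock genes and chaperones had 4 of 20 members higher and 0 lower, 7 when adjusted over the list alone, a median of 0.34 and a camera adjusted p of 0.0195. Their adjusted p was 0.274 with an estimated correlation. Hspb6 (2.23) and Cryab (1.60), small heat shock proteins, Unc45b (1.46), a myosin chaperone, and Chordc1 (1.65) rose. The adjusted p of the heat shock list was 0.0762 without WT 1, 0.110 without WT 2, 0.0515 without WT 4, 0.0706 without A17/+ 1 and 0.0591 without A17/+ 2, with medians from 0.18 to 0.33. The call was also lost at a mean count of 10 or more (0.0857, median 0.19), with sample weights (0.0661, median 0.23), with the length trend removed (0.0667, median 0.23) and without both libraries numbered 1 (0.0843, median 0.28). It was lost on the genes of the deposited log2 values (0.132) and with limma-trend (0.304), where the median was 0.11. Genes of the unfolded protein and integrated stress response did not pass as a list (adjusted p = 0.920), with 0 of 16 members higher or lower by edgeR over all genes or adjusted over the list alone. Its median (0.01), mean (0.05) and fry were positive and camera was negative. Phgdh, of serine synthesis, had −0.92, and Atf5, a stress transcription factor, had 1.18, and neither passed.

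Of the lists of other cell types, smooth muscle and pericyte, fibroblast, adipocyte and macrophage markers passed by camera, and endothelial markers did not (adjusted p = 0.115). Smooth muscle and pericyte genes had 2 of 11 members higher and 0 lower, 5 when adjusted over the list alone, a median of 0.52 and a camera adjusted p of 0.0153. The adjusted p was 0.265 with an estimated correlation. With the preset correlation it was 0.0762 without WT 2 (median 0.44), 0.0882 without WT 3 (median 0.42) and 0.0589 without both libraries numbered 1 (median 0.78). It was 0.0828 on the genes of the deposited log2 values and 0.209 with limma-trend, where the median was 0.26. Tpm2 (0.89), a tropomyosin that striated muscle also makes, and Acta2 (1.13), smooth muscle actin, rose. Fibroblast genes had 3 of 14 members higher and 0 lower, 5 when adjusted over the list alone, a median of 0.42 and a camera adjusted p of 0.0195. Their adjusted p was 0.270 with an estimated correlation. Dcn (2.24), the matrix proteoglycan decorin, Gsn (0.82), the actin-severing gelsolin, and Fbn1 (0.82), fibrillin, rose.

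Adipocyte genes had 3 of 10 members higher and 0 lower, 3 when adjusted over the list alone, a median of 0.29 and a camera adjusted p of 0.0410. The adjusted p was 0.202 with an estimated correlation. Fabp4 (2.68), a fatty acid carrier, Lpl (1.17), lipoprotein lipase, and Plin4 (1.18), a lipid droplet protein, rose. This list had an adjusted p of 0.110 without WT 2, 0.0910 without WT 3, 0.0745 without WT 4, 0.179 without A17/+ 1, 0.0556 without A17/+ 3 and 0.0551 without A17/+ 4. Its medians there ran from 0.12 without A17/+ 4 to 0.31 without A17/+ 1. The call was also lost with limma-voom (0.0959, median 0.25), at a mean count of 10 or more (0.0857, median 0.15), with the epithelium covariate (0.0627, median 0.31) and with sample weights (0.0561, median 0.53). It was lost on the genes of the deposited log2 values (0.132, median 0.06), with limma-trend (0.328, median 0.14) and without both libraries numbered 1 (0.166, median 0.55). Macrophage and leukocyte genes had 1 of 7 members higher, the antigen presentation gene H2-Ab1 (1.20), and 0 lower, 1 when adjusted over the list alone, a median of 0.57 and a camera adjusted p of 0.0410. With an estimated correlation the adjusted p was 0.202, and with the preset correlation it was 0.105 without A17/+ 1, 0.0526 without A17/+ 2, 0.0723 with the epithelium covariate, 0.113 with the length trend removed and 0.0744 without both libraries numbered 1. The macrophage median stayed between 0.56 and 0.66 in these settings.

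Genes of nuclear polyadenylation, the process in which PABPN1 acts, had 1 of 23 members higher and 0 lower, 1 and 0 when adjusted over the list alone (median −0.18, camera adjusted p = 0.533). The member that rose was Pabpc4 (1.09), a cytoplasmic poly(A)-binding protein. Splicing and hnRNP factors had 0 of 35 members higher and 1 lower, Srsf10 (−0.77), a splicing regulator, and 0 when adjusted over the list alone (camera adjusted p = 0.645). The median (0.05) and mean (0.03) of the splicing list were positive, and camera and fry pointed down.

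Genes of the stratified tongue epithelium moved in both directions. Of 33 members 7 fell and 1 rose, 8 fell and 6 rose when adjusted over the list alone, and the list did not pass (median −0.12, mean 0.17, camera adjusted p = 0.179). The desmosome genes Dsp (−0.85), Dsc3 (−0.71) and Perp (−0.72) and the cornified layer gene Sbsn (247 ± 49.1 CPM in WT, 123 ± 10.8 in A17/+, SD, n = 4) were the members with the smallest p. The other members that fell, Krt76 (−0.72), Cdh1 (−0.97) and Dsg3 (−0.69), and the 1 that rose, the cornified envelope gene Sprr3 (2.60), were chosen after their values were seen. The keratins Krt13 (0.68, adjusted p = 0.0501) and Krt4 (0.38, adjusted p = 0.227), also chosen then, did not pass. The list took 2.25% ± 0.146 of counts in WT and 2.11% ± 0.560 in A17/+ (SD, n = 4; exact permutation p = 0.629). It had an adjusted p of 0.0324 and a median of −0.20 without A17/+ 2, 0.0401 with the length trend removed, and a median of 0.09 without A17/+ 1.

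**Figure D3:**
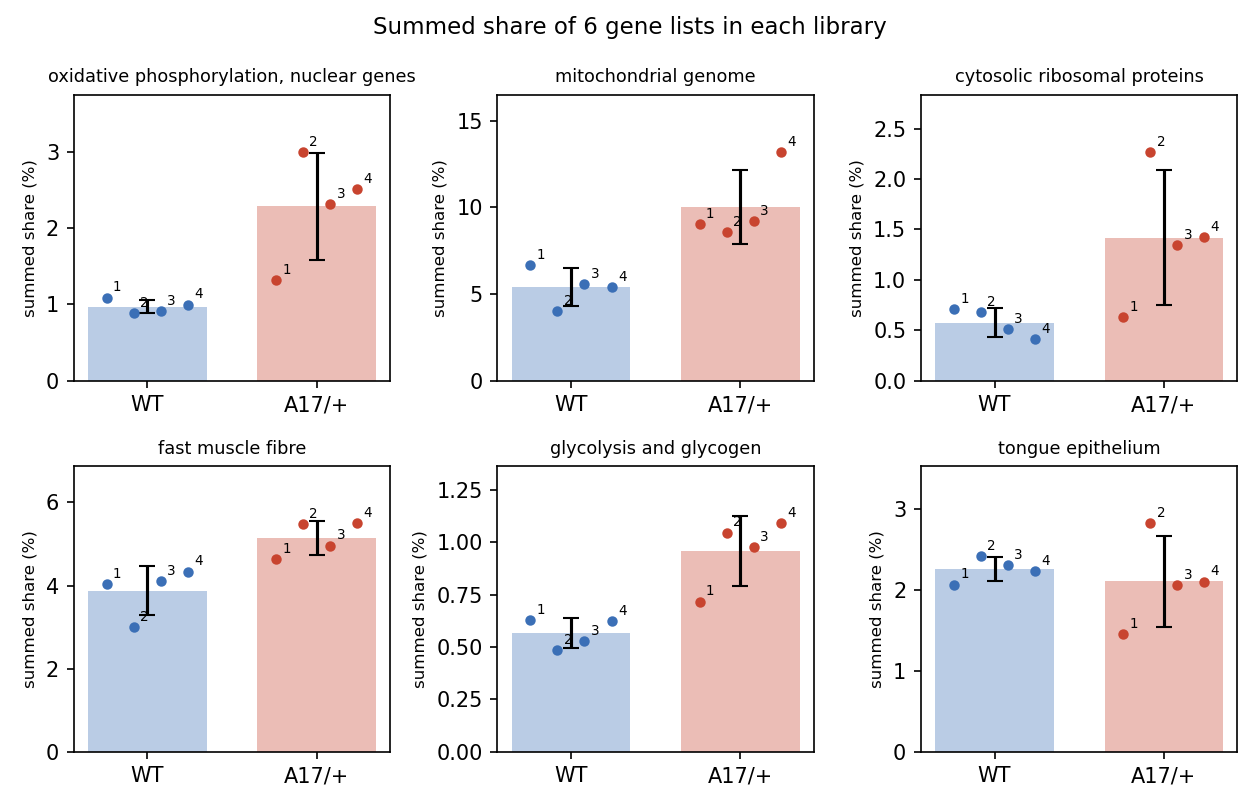
Share of the TMM-scaled counts, in percent, taken by the members of each gene list in each library, with bars at the mean, error bars of 1 SD (n = 4) and points numbered by replicate. For oxidative phosphorylation and ribosomal proteins A17/+ 1 lies lowest of its genotype, at 1.32% and 0.627%.

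The fold change also followed transcript length. Across genes, which are not independent replicates, the Spearman rho of log2 fold change with transcript length was −0.271, and with GC content 0.0221. Genes under 600 nt had a median log2 fold change of 1.98, and 0.59 with the oxidative phosphorylation and ribosomal protein lists left out. Genes of 6000 nt or more had a median of −0.11. The median transcript length was 1429 nt for the genes higher, 4109 nt for the genes lower and 3527 nt for all tested. Within libraries, rho of the level against the mean of all libraries with length was 0.122, 0.191, 0.173 and 0.224 in WT 1 to 4 and 0.0629, −0.325, −0.226 and −0.199 in A17/+ 1 to 4. With the length trend removed the median was 1.79 for oxidative phosphorylation and 0.91 for ribosomal proteins, and both kept their camera calls, while 3 lists lost theirs and the tongue epithelium list gained a lower one (adjusted p = 0.0401, median −0.31). The proteasome list went to an adjusted p of 0.285 and a median of 0.13 from 0.30, the heat shock list to 0.0667 and 0.23 from 0.34, and the macrophage list to 0.113 with a median of 0.56 against 0.57.

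**Figure D4:**
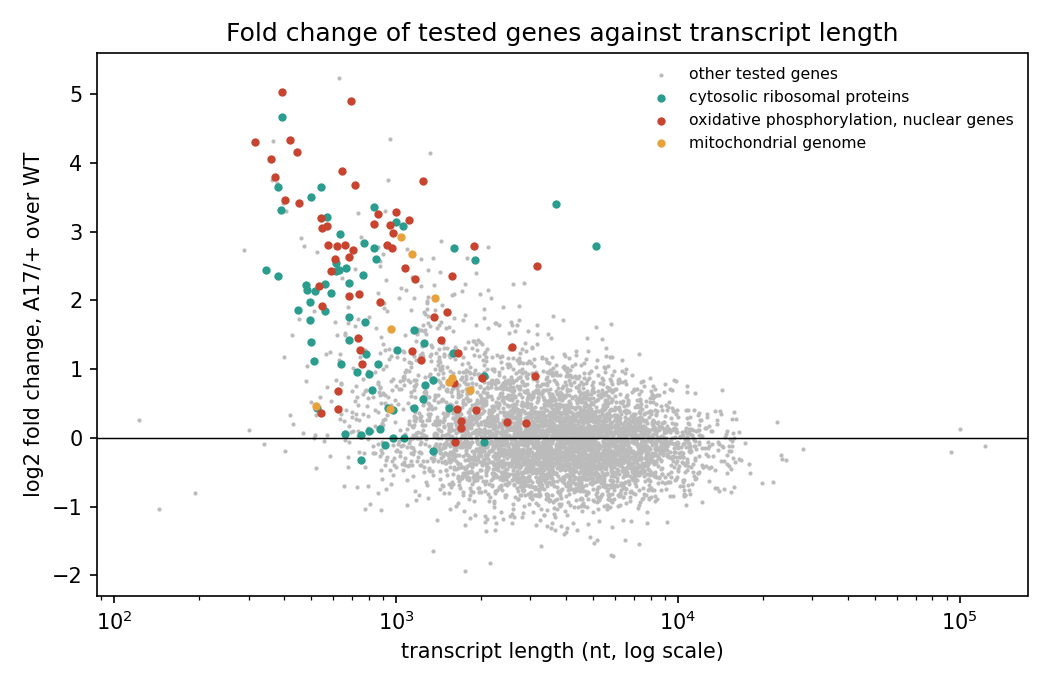
Log2 fold change, A17/+ minus WT, of each tested gene against its transcript length in nt on a log axis, with oxidative phosphorylation, ribosomal protein and mitochondrial genome genes in colour. Genes under 600 nt have a median of 1.98 and genes of 6000 nt or more a median of −0.11.

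In total 14 of 30 lists were higher and 0 lower by camera, against 15 higher and 1 lower at an unadjusted p under 0.05 and 18 higher and 0 lower by fry. With an estimated correlation 0 lists passed, with a smallest adjusted p of 0.163 and 6 lists at an unadjusted p under 0.05. Of the 35 ways to split the 8 libraries into equal groups, 3 gave 14 lists or more, the genotypes included.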

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

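The tests on transcript length, muscle tissue, epithelium, gland tissue and the split of the gene count were chosen after the results they measure were seen, the test by thinning was added after the data were seen but before its own result, and the test by splits of the list count was chosen before its result. Of 270 groups of 4 libraries checked for a library far from the others, 12 had one, against 13.5 expected at 1 in 20.

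Salivary gland transcripts stood out in WT 1, where the list of lingual gland genes summed to 941 counts, 0.202% of the library, against 1 to 7 in the other WT libraries and 10 to 28 in A17/+. Gland tissue in the sections of WT 1 is a candidate source: 7 of the 9 gland genes with at least 5 counts were highest there, the most abundant, chosen after their values were seen, being Lipf (418), Dmbt1 (239) and Bpifb1 (188). The limit of 5 was set on counts summed over all libraries, which such genes passed through WT 1 itself. The 7 of 9 are therefore no support separate from the sum. Of the 132 genes lower in A17/+, 124 stayed lower and past the threshold without WT 1, so those calls do not rest on WT 1 alone. A gene high only in WT 1 varies widely within WT and is thereby hard to call, and 0 gland genes were tested. The 124 therefore cannot decide whether gland tissue was a source of genes lower in A17/+. A difference between the mice themselves stays open and was not tested.

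Oxidative phosphorylation genes rose, and other transcripts under 1000 nt took 3.63% ± 0.443 of counts in WT and 5.05% ± 1.03 in A17/+ (SD, n = 4; exact permutation p = 0.0857), with 3.82% in A17/+ 1, inside the WT range. Outside the oxidative phosphorylation, ribosomal protein and mitochondrial lists, the Spearman rho of level with length was 0.134 ± 0.0379 in WT and −0.143 ± 0.135 in A17/+ (SD, n = 4; exact permutation p = 0.0286). Against length as its whole cause, 0 of 10000 random lists matched for length and level had a median as high as 2.48, with a highest of 1.15. For ribosomal proteins it was also 0 of 10000, with a highest of 1.22. The fatty acid oxidation, glycolysis, calcium handling and fibroblast lists also had 0 of 10000. For the fast fibre, smooth muscle, atrophy and heat shock lists 0.01%, 0.22%, 0.55% and 2.56% of such lists were as high. For the proteasome, macrophage and adipocyte lists 11.1%, 13.8% and 5.23% were as high. Genes of a random list were drawn separately, while oxidative phosphorylation and ribosomal members vary together (estimated correlation 0.579 and 0.674). The test thus shows a rise above other genes of like length and level. Its counts do not measure chance between libraries, nor exclude an effect of RNA quality. Against fewer UMIs in the WT libraries, the median was 2.07 with every library thinned to the smallest total. For more muscle tissue in the A17/+ sections, 35 muscle genes with transcripts of 4000 nt or more had a median of 0.23 (SD 0.37), below 2.48. They cannot decide the question, because tested genes of such lengths ran low in A17/+. Medians were −0.07 from 4000 to 6000 nt and −0.11 from 6000 nt up. The fast fibre list had a median of 0.89. More muscle tissue, a partial effect of RNA quality or library preparation, for which the labels give no batch, and the genotype all stay open. The length-removed median of 1.79 may still hold part of each.

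Part of the tongue epithelium list fell. Less epithelium in the A17/+ sections would move the members alike. With the length trend removed they moved apart, and the SD between their log2 fold changes was 3.51 times their median SE. Members of a list can also differ for reasons of their own, so this spread cannot exclude less epithelium as a part of the cause. In the same fit the list as a whole was lower (camera adjusted p = 0.0401, median −0.31). Against transcript length, 6 of the 7 members that fell stayed past the threshold with the length trend removed. A change within the epithelium that accompanies the genotype, or a different region of the tongue in the sections, may explain it and neither was tested.

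The other values far from the rest of their group were as follows. Cry2 had 135 CPM in WT 4 and 42.0 to 50.8 in the other WT libraries. Rbm15b had 15.6 CPM in A17/+ 1, Tpm3 93.2 in A17/+ 2 and Eif3m 70.6 in A17/+ 2. Psmc6 had 51.3 CPM in WT 1, above the other WT libraries, and 51.3 in A17/+ 1, below the other A17/+ libraries. Uqcrb had 95.8 CPM in WT 1, Ndufs6 29.1 in WT 2, and Gsn 562 in WT 1. Transcripts of the mitochondrial genome took 13.2% of the TMM-scaled counts in A17/+ 4 and 8.57% to 9.21% in the other A17/+ libraries. The Schwann cell list took 0.0209% in A17/+ 2, the highest of its genotype.

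For the number of genes that changed, of the 35 splits of the libraries only the genotypes gave 453 or more, and the highest other gave 282. A share of 1 in 35 is the smallest that this test can give, so chance is unlikely but not excluded. For the number of lists chance cannot be excluded: 3 of the 35 splits gave the 14 lists or more, and the highest other gave 15 lists, with WT 4 and A17/+ 1 exchanged.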

How the results depend on the processing

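The alternatives with the length trend removed, thinned counts, the deposited log2 genes or values, and both libraries numbered 1 left out were chosen after the data were seen. None of the 88 named genes past the threshold and none of the 14 lists that passed changed direction in any setting that gave it a value. Pabpn1, not past the threshold, did. Of the single-gene results under settings other than leaving out a library, 1315 kept their side of the threshold, 102 lost and 28 gained it. For lists 453 kept their side and direction, 35 lost and 13 gained the call, and 5 turned direction without passing. The count of 453 genes (321 higher, 132 lower) was 228 (145, 83) with limma-voom, sharing 227 genes, 853 (615, 238) with no filter, 829 (374 lower) with sample weights, 293 (66 lower) when thinned, 730 (484, 246) on the genes of the deposited log2 values, 797 (538, 259) with limma-trend, 1025 (695, 330) without both libraries numbered 1, and 775 (487, 288) at an adjusted p under 0.1. Lower genes numbered 289 with library totals only and 217 with the epithelium covariate. Lists numbered 23 with no filter (22 higher, 1 lower), and 0 changed or higher with an estimated correlation. The lower list was immediate early genes with no filter, and 1 list was lower with the replicate block and the epithelium covariate (immediate early genes) and with the length trend removed (tongue epithelium). The fewer genes tested (3087) go with the thinned count, and more genes (19857) with no filter. For the rest the cause was not tested. Leaving out each library in turn gave 210 to 890 genes, 172 to 586 higher, 38 to 383 lower, 10 to 15 lists, 10 to 15 higher, and 0 to 2 lower. Pabpn1 (−0.12) ranged from −0.39 to 0.0326 without each library, was 0.52 thinned (exact permutation p 0.429) and 0.11 without both libraries numbered 1 (exact permutation p 0.900), and −0.63 with the length trend removed. These Pabpn1 values mix log2 ratios of mean CPM with edgeR log2 fold changes. Both ends of the range and the value with the length trend removed are edgeR fits. Camera turned direction for lists that did not pass. The unfolded protein response did so with medians of 0.000485 at a mean count of 10 or more and 0.0220 without both libraries numbered 1. Without each library its median ran from −0.141 to 0.0413. On the reported fit, with a median of 0.00948, fry pointed up for this list and camera down, and this is 1 of the 5 turns above. Slow fibres turned with 0.16 with the length trend removed. Tongue epithelium did so with 0.0145 without both libraries numbered 1 and −0.201 to 0.0877 without each library. The neuromuscular junction list had 0.0119 to 0.330 without each library. The cause was not tested. After each genotype's mean was taken out, 0 of 4 pairs of libraries with equal numbers had a residual correlation over 0.1, although the levels of WT 1 and A17/+ 1 were close (r = 0.927), and the block gave 410 genes. The salivary gland covariate was not run because 0 of its genes were tested. Depth limits Pabpn1, at 4 to 15 counts a library, and small changes: 54% of simulated 2-fold changes were recovered.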

Other observations

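The permutation test of Alas2 was chosen after the data were seen, and the tests of the lists were planned. Of the erythrocyte list only Hbb-bs was tested, and no test of the list was made. Hba-a1, Hba-a2 and Hbb-bt, below the filter and chosen after their values were seen, summed to 6, 5 and 1 counts over the WT libraries and 209, 113 and 63 over the A17/+ libraries, with reads shared among near-identical copies. A17/+ 2 held 106 of the Hba-a1 counts and 45 of those of Hbb-bt, and A17/+ 1 held 6 and 2. Alas2, a haem synthesis enzyme of red cells also chosen after its values were seen, had 9 counts in WT and 27 in A17/+ (exact permutation p = 0.200). Of 4 interferon response genes tested, B2m (log2 fold change 2.78) and H2-K1 (1.15), of antigen presentation, rose and 0 fell, and 3 rose when adjusted over the list alone.

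Circadian clock genes moved in both directions. Of 15 members 3 fell, the repressors Cry2 (−1.81), Per2 (−1.30) and Ciart (−1.19, chosen after its value was seen), and 2 rose, the repressor Nr1d1 (1.17) and the protease Usp2 (1.06), against 4 and 2 when adjusted over the list alone. The list did not pass (median −0.21, camera adjusted p = 0.159), and it had an adjusted p of 0.0474 without WT 3 and 0.0334 without A17/+ 4. The output gene Dbp, chosen after its value was seen, had 1.03 (adjusted p = 0.229). The time of day of sampling is not given in the labels. Immediate early genes, which respond to handling of tissue, had 0 of 7 members changed over all genes by edgeR and 3 lower when adjusted over the list alone (median −0.65, camera adjusted p = 0.0927). The list had an adjusted p of 0.0414 without A17/+ 2, 0.0375 with the replicate block, 0.0376 with the epithelium covariate and 0.0265 with no filter, where its median was 0.000932. Ier5 had −1.58 and Nr4a2 −1.05, and neither passed over all genes.

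Lists that did not pass as a whole held single genes that did. Of 6 satellite cell and regeneration genes, H19 (1.13), a non-coding RNA of developing muscle, and Des (1.31), the intermediate filament desmin, rose, with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0969). Of 24 dystrophin complex genes 2 rose, Des among them, and 0 fell, with 2 higher when adjusted over the list alone (adjusted p = 0.115). Of 11 neuromuscular junction and denervation genes, Sln alone rose over all genes, with 1 higher and 1 lower when adjusted over the list alone (adjusted p = 0.783). Of 24 autophagy and lysosome genes, the cathepsins Ctsd (2.77) and Ctsb (1.45) rose, with 4 when adjusted over the list alone (adjusted p = 0.179). Of 31 extracellular matrix genes, Dcn, Sparc (1.58), Col3a1 (1.31) and Fbn1 rose and 2, of which Thbs2 is 1, fell, with 5 and 3 when adjusted over the list alone (adjusted p = 0.257).

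Of 10 senescence and p53 target genes, Igfbp5 and Ccng1 (0.99), a cyclin, rose and Aen (−0.95), a nuclease, fell, with 3 and 1 when adjusted over the list alone (camera adjusted p = 0.179). Of 11 glucocorticoid response genes, Glul (0.94), glutamine synthetase, rose, with 2 higher and 1 lower when adjusted over the list alone (adjusted p = 0.391). Of 13 endothelial genes, Fabp4, which the adipocyte list also holds, rose, with 1 when adjusted over the list alone (adjusted p = 0.115). Of 3 Schwann cell and nerve genes, Pmp22 (1.74), a myelin protein, rose, with 2 when adjusted over the list alone. The only taste cell gene tested, the calcium channel Itpr3, had −0.66 (adjusted p = 0.0744), and 1 fell when adjusted over the list alone. By fry, the dystrophin complex (adjusted p = 0.0133), endothelial (0.000994), autophagy (0.0211) and glucocorticoid (0.0427) lists were higher. By camera with no filter, the endothelial (adjusted p = 0.0428), autophagy (0.0296), senescence (0.0493) and extracellular matrix (0.0393) lists were higher.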
